A study of Mus musculus with 27 samples.

How the data were processed

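The samples are retinas of 27 mice, 6 to 8 weeks old, profiled by single-cell RNA sequencing with the Parse Biosciences WT V2 kit. The kit marks fixed cells by split-pool barcoding, without droplets. The labels give 9 groups of 3 mice, from 3 genotypes and 3 treatments. WT stands for C57BL/6J mice, DKO for Abca4-/-Rdh8-/- mice and PVR for Abca4PV/PVRdh8-/- mice, which carry a knock-in allele of Abca4. Unbleached mice were untreated. Bleached mice received vehicle (DMSO) or maraviroc at 60 mg/kg by intraperitoneal injection, in 60 µL. After 24 h in the dark and pupil dilation with 1% tropicamide, they were exposed to light of 10000 lux for 30 min, about 30 min after the injection. A contrast of bleached with unbleached mice is therefore one of the whole procedure, injection included. The time between light and tissue collection is not given in the sources used here.

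The authors deposited a matrix of 37725 genes by 69962 cells in units of ln, the natural log of 1 plus 10000 times the count over the total of the cell. They also deposited each cell's total counts, its number of genes, its mouse and 1 of 41 cluster numbers without cell type names. The submitters' notes name genome build GRCm39, R 4.2.2 and Seurat 4.3.0. The aligner, the counting tool and the cell filter are not given in the sources used here. The cell with the lowest total had 1469 counts, and the lowest number of genes in a cell was 458. Counts were expected when the comparisons were planned, and the matrix held log values instead. All 178451221 values (100%) inverted to whole counts with a tolerance of 1e-06, and these summed to the deposited total in 100% of the cells. The recovered counts were used throughout. Total counts per mouse ranged from 12327101 to 44546031, and cells per mouse from 1899 to 3406. Median counts per cell ranged from 3555.5 to 10684.

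The clusters were assigned to cell classes with marker lists fixed before the data were examined. A marker had to be detected in at least 10% of a cluster's cells and at least 2 times the mean of the other clusters, with 5 CPM (counts scaled to a common total, as usual for this unit) added to both. A class needed at least 3 such markers and a share of its markers at least 1.5 times that of the next class. In place of that share, at least 3 of its markers and none of the next class among the cluster's top 10 genes sufficed. The astrocytes were named by this second rule. A cluster with low counts and none of its class's markers in the top 10 stayed unnamed. Rods here are the 47327 rod-like cells of 8 clusters. Müller glia are 6346 cells of 4 clusters, bipolar cells 8644 of 14, cones 4207 of 2 and amacrine cells 968 of 4. Endothelial cells (736), pericytes and smooth muscle (173), horizontal cells (155), microglia and macrophages (141), ganglion cells (135) and astrocytes (105) came from 1 cluster each. The 3 clusters with 1025 cells that met no rule stayed unnamed. Clusters were drawn from the same expression values, so genes that separate 2 clusters of a class are not independent evidence. Percentages of a class by cluster are given beside the values for bleaching in DKO and PVR mice and for maraviroc in PVR mice, for the clusters named there. They pool the cells of the mice of a group, so mice with more cells weigh more, and they were not tested.

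Counts were summed per mouse and class, and the mouse was the replicate. Each class was tested where every group had at least 2 mice with at least 10 cells. The test was the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr and a model of the 9 groups. A Benjamini-Hochberg adjusted p under 0.05 was a call. All p values are two-sided. Log2 fold changes are given with their standard error (SE) and CPM as the mean with the standard deviation (SD) of 3 mice. CPM in contrasts are scaled by TMM. For each genotype, bleached vehicle mice were compared with unbleached mice and maraviroc with vehicle, and genotypes were compared without bleaching. Averages over genotypes or treatments and differences between genotypes in a response were contrasts of the same model.

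Named genes follow a rule fixed before the data were examined. It takes up to 10 called genes per direction with the largest change, an average log2 CPM of at least 3 and no overlap between the mice of both groups, and up to 10 called members of the fixed lists, lowest adjusted p first. Abca4, Rdh8, Adipor1 and Gfap are always included. Some genes that the rule selects are not reported here. Other members of lists that are named as examples were chosen after their values were seen. With 3 mice against 3, no overlap occurs by chance in 10% of genes. The fixed lists are rod phototransduction, cone phototransduction, retinoid visual cycle, ceramide synthesis, ceramide breakdown and conversion, chemokines and their receptors, cytokines and NF-kB, interferon response and antigen presentation, complement, reactive gliosis, Müller glia homeostasis, immediate early genes, heat shock, unfolded protein response, oxidative stress response, cell death, circadian clock, sterol synthesis and export, glycolysis, mitochondrially encoded genes, homeostatic microglia and reactive microglia. Lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a contrast and class. Camera with an estimated correlation and fry were alternatives.

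Shares of cell classes were compared with exact permutation tests (3 mice against 3, smallest p 0.1). Over genotypes they were compared with permutation tests that permuted treatment within genotype (100000 resamples), adjusted over 11 classes. Sex was read from Xist (female above 300 CPM). Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-image 0.26.0 and matplotlib 3.10.9 was used for the remaining steps.

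The pipeline was tested on simulated counts made from the gene means, depths and spread of all 27 mice. Changes of 1.5, 2 or 4 times were planted in a few genes of the WT vehicle group. In rods, 26.9%, 68.7% and 87.9% of the planted genes were called, and 6 of 128 calls (4.7%) were false. In Müller glia, 9.0%, 38.8% and 81.8% were called, and 3 of 89 calls (3.4%) were false. Alternatives planned in advance were RLE size factors, DESeq2 1.42.0, no filter, a stricter filter (minimum count 30), a fit of the compared mice alone, at least 50 cells per mouse, cells between percentiles 5 and 95 of depth, classes without genes over 5 times higher in rods, and leaving out each mouse. Added after seeing the data were limma on the deposited ln values, sex as a covariate, Müller glia without cluster 9 (low totals and photoreceptor RNA), and cells without the 5% of highest Scrublet scores per mouse. The last replaced the planned Scrublet calls, which covered 0.216% of cells. A planned block for replicate number was left out, because the loading IDs of the mice match no replicate number. Mice are named by group and loading ID. The title of 1 unbleached PVR mouse says that it was redone, and the loading IDs do not tell which mouse it was.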

Results

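RNA was counted in single cells of the retina of 27 mice, 3 in each of 9 groups. The 3 genotypes were WT, DKO (Abca4-/-Rdh8-/-) and PVR (Abca4PV/PVRdh8-/-), and the 3 treatments were unbleached, bleached with vehicle and bleached with the drug maraviroc. Abca4 transports retinoids in photoreceptor outer segments and is the gene altered in Stargardt disease, and Rdh8 is a retinol dehydrogenase of photoreceptors. Total counts per mouse ranged from 12327101 to 44546031, and median counts per cell from 3555.5 to 10684. The PVR vehicle mice had median counts per cell of 10398 (S25), 6747 (S26) and 10684 (S27). All 9 WT mice and 10 other mice were female by their Xist level, and the remaining 8 were male. Each group holds 3 mice unless stated, fold changes are log2 values with the SE, and levels are CPM with the SD. In the called genes named below, the mice of both groups did not overlap except where stated, which chance gives in 10% of genes.

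Transcripts of both edited genes were compared between genotypes first. In rods of unbleached mice, Abca4 was at 2790 ± 30.6 CPM in WT, 732 ± 148 in DKO and 2860 ± 129 in PVR mice. Rdh8 was at 88.3 ± 3.19 CPM in WT, 18.7 ± 3.84 in DKO and 26.0 ± 4.7 in PVR mice. After bleaching with vehicle, Abca4 in rods was at 2890 ± 138 CPM in WT, 595 ± 10 in DKO and 1700 ± 75.5 in PVR mice. With maraviroc it was at 2730 ± 277, 756 ± 259 and 2210 ± 609 CPM. The fall of Abca4 in PVR rods on bleaching passed the test (-0.84 ± 0.21, adjusted p = 0.00411), and its difference between maraviroc and vehicle in PVR rods did not (0.45 ± 0.21, adjusted p = 0.298).

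**Figure D1:**
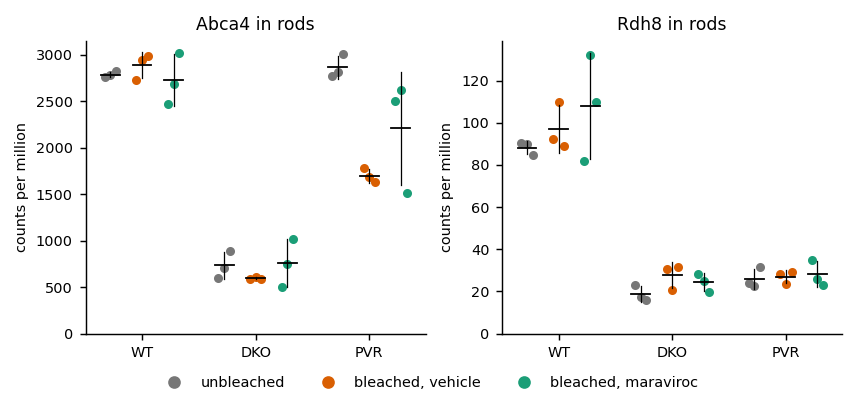
Abca4 and Rdh8 in rods, in CPM of the rod counts of each mouse (points), with the mean and SD of 3 mice (lines), by genotype and treatment. Rdh8 is near 88.3 in unbleached WT mice, 18.7 in DKO and 26.0 in PVR mice, and Abca4 is low in DKO mice of each treatment.

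Before bleaching, rods of both mutants shared large differences from WT rods. Col5a3, a collagen chain, was higher by 4.27 ± 0.35 in DKO and 3.93 ± 0.34 in PVR rods, and Fzd3, a Wnt receptor, by 3.05 ± 0.24 and 2.96 ± 0.24. Enox1 was lower by -4.03 ± 0.2 and -4.23 ± 0.2, Rab6b by -4.19 ± 0.51 and -4.31 ± 0.5, and the growth factor Fgf2 by -1.19 ± 0.26 and -1.23 ± 0.26. Set apart from DKO rods, PVR rods had higher Rtkn2 (5.36 ± 0.39) and the cytokine Il18 (3.64 ± 0.38, from 3.04 ± 0.645 to 38.3 ± 2.95 CPM). They had lower Myo7a, an unconventional myosin altered in Usher syndrome (-4.82 ± 0.48), and lower Guca1b, an activator of guanylate cyclase in phototransduction (-1.61 ± 0.14, from 618 ± 94.7 to 203 ± 38.9 CPM). Of 21 glycolysis genes, 3 were lower in PVR than WT rods over all genes tested and 10 adjusted over the list alone, with Gpi1 at -1.06 ± 0.16 and Eno1 at -0.65 ± 0.16. The list had a median of -0.54 (camera adjusted p = 1.15e-05; adjusted p = 0.847 with an estimated correlation). Of 14722 genes in rods, 112 were higher and 161 lower in DKO than in WT, 320 and 302 in PVR than in WT, and 161 and 106 in PVR than in DKO. DKO and PVR rods shared 77 higher and 110 lower genes relative to WT, where 20 simulations with the shared WT group but no difference between genotypes gave at most 1 of each. With no difference simulated, few genes are called in either contrast, so a low overlap was fixed in advance. The simulations do not test whether a deviation of the shared WT mice gives such an overlap. The labels give a C57BL/6J background for all 3 genotypes and add the word Leu, which they do not explain, for DKO mice. Both mutants are Rdh8-/-, and a local effect of the edited alleles or their flanking DNA on single named genes, such as Col5a3, was not tested. The sexes also differ, since all WT mice were female. The barcodes place each of the 3 unbleached WT mice in 2 loading wells and each of the other 24 mice in 1.

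In Müller glia, the main support cells of the retina, unbleached PVR mice had lower levels of sterol synthesis genes than WT. Of 20 measured genes of the list, 9 were lower over all genes tested, and 13 were lower and 1 higher adjusted over the list alone. Idi1 was lower by -3.13 ± 0.53 (54.4 ± 13.9 to 6.77 ± 3.34 CPM), Hmgcs1 by -1.96 ± 0.4 and Srebf2, the regulator of the pathway, by -0.68 ± 0.15. The median of the list was -0.91 (camera adjusted p = 3.79e-10; adjusted p = 0.089 with an estimated correlation; fry adjusted p = 0.00272). Heat shock genes had 3 of 14 members lower, among them Cryab (-2.14 ± 0.33) and Hspa8 (-1.74 ± 0.29), with a median of -0.94 (camera adjusted p = 1.04e-07; adjusted p = 0.278 with an estimated correlation). Rod phototransduction genes in the same cells had a median of 0.65, with none of 23 called over all genes tested and 6 higher adjusted over the list alone (camera adjusted p = 6.21e-09; adjusted p = 0.392 with an estimated correlation). Anxa1, an annexin, was at 207 ± 91.4 CPM in WT, 206 ± 19.2 in DKO and 8.48 ± 8.23 in PVR Müller glia. Col5a3 was again higher in both mutants (4.39 ± 0.31 in DKO and 4.52 ± 0.32 in PVR). Of 14571 genes, 40 were higher and 36 lower in DKO than in WT, 146 and 258 in PVR than in WT, and 32 and 45 in PVR than in DKO. These totals depend on single mice. The total of 404 for PVR and WT was 154, 187 and 1201 without WT mice S10, S11 and S12, and 182, 256 and 214 without PVR mice S16, S17 and S18. The total of 76 for DKO and WT was 44 without S10, 48 without S11, 49 without S14 and 42 without S15. The total of 77 for PVR and DKO was 40, 119 and 29 without DKO mice S13, S14 and S15 and 36, 39 and 24 without PVR mice S16, S17 and S18.

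Cones of unbleached mutants had higher immediate early genes, which neurons induce with activity, than WT cones, and PVR cones had lower glycolysis genes. Of 18 immediate early genes, 6 were higher in DKO and 7 in PVR cones, and 10 and 12 adjusted over the list alone, with none lower. Fos was higher by 1.35 ± 0.19 in DKO and 1.66 ± 0.19 in PVR cones, Fosb by 1.8 ± 0.31 and 2.42 ± 0.31, and Egr3 by 2.83 ± 0.59 and 4.15 ± 0.54. The medians were 0.81 and 1.14, and both calls held with an estimated correlation (adjusted p = 0.00856 and adjusted p = 0.000918). Both contrasts use the same unbleached WT mice, so they are not independent, and a deviation of those mice would show in both. Of 21 glycolysis genes, 5 were lower in PVR cones and 9 adjusted over the list alone, with Gpi1 at -1.31 ± 0.17, Aldoa at -1.07 ± 0.21 and Eno1 at -0.99 ± 0.18 (median -0.6; adjusted p = 0.0295 with an estimated correlation). In DKO cones 1 of 21 was lower (median -0.19; camera adjusted p = 0.00574; adjusted p = 0.541 with an estimated correlation). Slc24a2, the cation exchanger of cones, was at 1840 ± 136 CPM in WT, 785 ± 95.9 in DKO and 649 ± 39.3 in PVR cones. Pde6h, the inhibitory subunit of the cone phosphodiesterase, was at 893 ± 103 in WT, 874 ± 57.9 in DKO and 312 ± 31.7 in PVR cones. Lrat, an acyltransferase of the retinoid cycle, was higher by 4.41 ± 0.65 in DKO and 3.92 ± 0.68 in PVR cones. At the same time 5 of 23 rod phototransduction genes were higher in PVR than WT cones, among them Cnga1 (1.7 ± 0.35; median of the list 0.18; camera adjusted p = 0.000506; adjusted p = 0.591 with an estimated correlation). Of 11434 genes in cones, 48 were higher and 65 lower in DKO than in WT and 162 and 142 in PVR than in WT. The total of 113 for DKO was 69, 74 and 74 without WT mice S10, S11 and S12, 72 without S13 and 62 without S14, and the total of 304 for PVR was 183 without S10 and 187 without S16.

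Bleaching with vehicle was then compared with no treatment in each genotype. In WT mice edgeR called 0 genes in rods, Müller glia, cones and bipolar cells. Unadjusted p values under 0.05 numbered 320, 348, 308 and 350, and DESeq2 and limma called 0 in each. Without the filter on low counts edgeR called 19, 31, 10 and 24. Gfap, the filament protein of reactive glia, stayed near its unbleached level in WT Müller glia (18.8 ± 3.1 CPM against 19.7 ± 11.5; -0.12 ± 0.69).

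In DKO rods, single genes of cytokine signalling and of the early response to stimuli rose after bleaching. Stat3, a transcription factor of cytokine signalling, rose from 75.7 ± 11.6 to 394 ± 184 CPM (2.39 ± 0.42). Junb rose by 2.4 ± 0.53, the orphan receptor Nr4a1 by 1.94 ± 0.39, the NF-kB subunit Rela by 0.91 ± 0.2 and Myd88, an adaptor of innate immune receptors, by 2.03 ± 0.45. Pdzph1 (-0.92 ± 0.19) and Slc9a7 (-0.82 ± 0.2) fell. In DKO Müller glia, Gfap rose from 13.7 ± 9.21 to 156 ± 96.2 CPM (3.47 ± 0.69), Serpina3n, an inhibitor of serine proteases, from 1.54 ± 0.241 to 62.0 ± 19.3, and Vim, another glial filament, from 93.9 ± 12.4 to 290 ± 80.5. Complement C4b rose from 5.49 ± 1.68 to 47.6 ± 17.9 CPM, and Slc16a1, a lactate transporter, fell (-0.96 ± 0.15). Of 24 gliosis genes in Müller glia, 4 rose, and 15 adjusted over the list alone (median 1.61; camera adjusted p = 2.87e-15; adjusted p = 0.124 with an estimated correlation; fry adjusted p = 0.0256). Of 7 complement genes, 2 rose, and 5 adjusted over the list alone (median 1.24; camera adjusted p = 7.85e-06; adjusted p = 0.124 with an estimated correlation). In rods, 5 of 23 gliosis genes rose, and 8 adjusted over the list alone (camera adjusted p = 2.49e-08). Interferon genes had none of 23 called over all genes tested and 6 higher adjusted over the list alone (median 1.63; camera adjusted p = 2.21e-06), and 3 of 25 immediate early genes and 1 of 23 unfolded protein response genes rose (camera adjusted p = 0.000184 and 7.31e-05). Each of these 4 lists had an adjusted p of 0.638 with an estimated correlation. Bleaching raised 181 and lowered 34 genes in DKO rods and raised 61 and lowered 8 in Müller glia. In cones and bipolar cells edgeR called 0, with 925 and 1073 unadjusted p values under 0.05, 25 and 11 calls by DESeq2 and 2 and 0 by limma, and 96 and 36 calls without S22 and 174 and 261 without the filter. These counts rest on few mice. The 215 genes in rods became 0, 0 and 37 without unbleached mice S13, S14 and S15 and 843, 46 and 0 without vehicle mice S22, S23 and S24. The 69 in Müller glia became 0 without S13, S14, S15, S23 or S24 and 300 without S22. In rods limma called 0 and DESeq2 405. By deposited cluster, cluster 4 held 67.06% of DKO Müller glia before and 17.73% after bleaching, cluster 7 held 16.39% and 44.91%, and cluster 8 none and 15.41%. Cluster 2 held 2.4% and 18.74% of DKO rods.

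PVR rods had a far larger set of changed genes, with interferon and gliosis genes among them. RNA of other cells in the rod counts was not separated from that of the rods. Irf1, a transcription factor of the interferon response, was at 0.395 ± 0.0718 CPM in unbleached and 25.1 ± 3.45 in bleached PVR rods (5.91 ± 0.89), and Irf9 went from 5.34 ± 0.647 to 82.1 ± 1.58. Bcl3, a regulator of NF-kB, went from 0.643 ± 0.0978 to 41.3 ± 2.91 CPM, and Edn2, an endothelin that injured photoreceptors make, from 0.519 ± 0.45 to 33.0 ± 6.58. Ripk1, a kinase of inflammatory and cell death signalling, rose by 2.68 ± 0.4 and Rela by 1.27 ± 0.2. Pde6b, a subunit of the rod phosphodiesterase, fell from 2390 ± 28.9 to 1260 ± 82.4 CPM (-0.92 ± 0.16), and the channel subunit Cnga1 fell by -0.85 ± 0.17.

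By list, all 23 measured interferon genes rose in PVR rods (median 4.2; camera adjusted p = 1.38e-15; adjusted p = 0.154 with an estimated correlation). Measured genes of a list are those that passed the filter on low counts in the class. A gene can pass it through the bleached mice alone, so this share and median are partly set by the filter. Of 23 gliosis genes 21 rose (median 2.3), as did 14 of 25 immediate early genes, among them Junb (3.16 ± 0.52), 12 of 23 genes of the unfolded protein response, among them Ddit3 (0.94 ± 0.25), and 3 of 5 complement genes. Oxidative stress genes had 8 of 19 higher, with Gclm, of glutathione synthesis, at 1.33 ± 0.22. Of 12 cytokine genes 7 rose and 2 fell, among the latter Tnfaip3, an inhibitor of NF-kB (-1.48 ± 0.26). Cell death genes had 6 of 15 higher and 2 lower, and 5 of 8 reactive microglia genes rose. Rod phototransduction genes fell in 15 of 23 cases, and clock genes in 6 of 19, among them Rorb (-1.05 ± 0.22). Müller glia homeostasis genes had 3 of 16 higher. These 12 lists passed camera, with adjusted p between 0.154 and 0.447 with an estimated correlation, so none of the 12 held there. The lists of cone phototransduction, retinoid cycle, heat shock, sterol synthesis, glycolysis, mitochondrial genes, chemokines, homeostatic microglia and both ceramide lists did not pass camera. In the same mice Müller glia went from 4.74% to 19.12% of the cells and microglia from 0.14% to 0.45%. Glial RNA in the rod counts was not tested, so the gliosis, homeostasis and microglia genes need not be the rods' own. In all, 1889 genes rose and 1703 fell. Leaving out 1 mouse gave totals from 2434 (without S27) to 3301, and DESeq2 called 3539 and limma 3952. By deposited cluster, cluster 0 held 81.1% of unbleached and 7.2% of bleached PVR rods and cluster 2 held 2.7% and 62.0%. Cluster 6, which has interferon genes among its top 10 genes, held 2.0% and 15.42%.

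**Figure D2:**
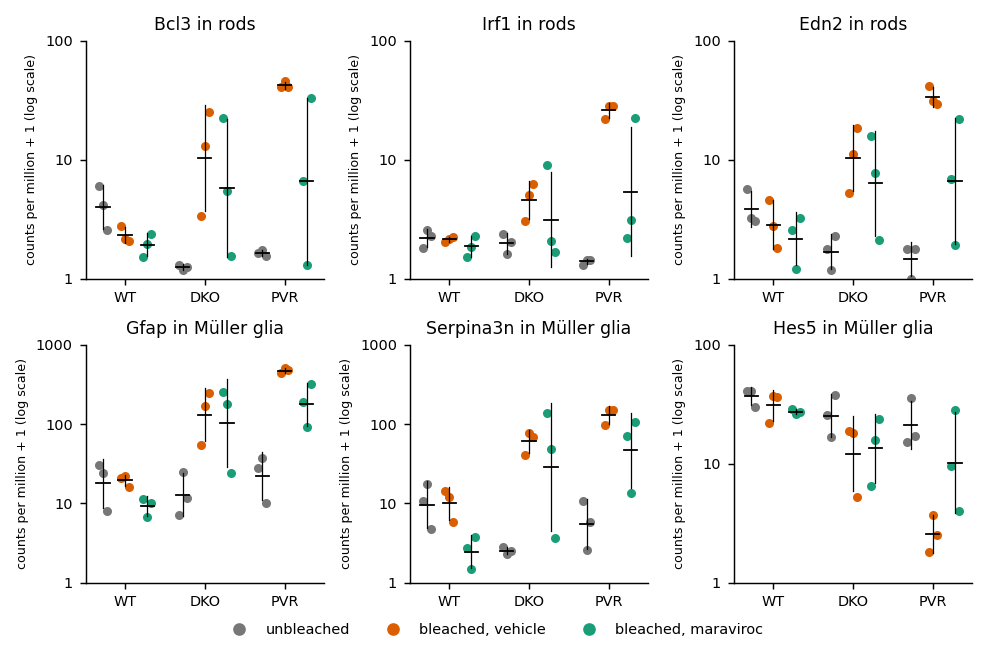
CPM plus 1 of the summed class counts of each mouse (points, log axis) for Bcl3, Irf1 and Edn2 in rods and Gfap, Serpina3n and Hes5 in Müller glia, with the mean and SD of the log values (lines), by genotype and treatment. In PVR mice Irf1 goes from 0.395 to 25.1 with bleaching and Hes5 from 21.8 to 1.69, and the PVR maraviroc mice differ from each other.

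In PVR Müller glia, bleaching was followed by gliosis and the loss of homeostatic genes. Gfap rose from 24.3 ± 14.0 to 476 ± 34.2 CPM (4.36 ± 0.71), Vim from 84.5 ± 4.0 to 577 ± 81.7 and Serpina3n from 5.45 ± 4.16 to 133 ± 32.1. Lif, a cytokine that Müller glia make after photoreceptor injury, was at 0.205 ± 0.356 CPM before and 38.5 ± 4.18 after bleaching. Glul, the enzyme that converts glutamate to glutamine, fell from 5930 ± 344 to 893 ± 412 CPM, Rlbp1, a retinoid carrier, by -1.34 ± 0.28 and Hes5, a Notch target, from 21.8 ± 11.5 to 1.69 ± 0.98 CPM. Gliosis genes rose in 19 of 24 cases and fell in 1 (median 3), and homeostasis genes fell in 11 of 17 and rose in 1 (median -1.06). Of 9 reactive microglia genes 8 rose, among them Axl, a receptor for dying cells (2.18 ± 0.29), and Ctsd, a lysosomal protease (1.65 ± 0.34). Interferon genes rose in 16 of 28 cases, cytokine genes in 12 of 15 (2 fell), complement genes in 4 of 7 and immediate early genes in 9 of 26. The unfolded protein response had 15 of 23 members higher, with Hspa5, its chief chaperone, at 1.75 ± 0.39, and oxidative stress 10 of 22 higher and 1 lower, with Hmox1, heme oxygenase, at 4.81 ± 1.14. Heat shock genes rose in 5 of 14 cases and fell in 1, and cell death genes rose in 6 of 17, with Casp8 at 2.4 ± 0.37. Clock genes fell in 10 of 19 cases, with Arntl, a core clock factor, at -1.14 ± 0.18. Retinoid cycle, sterol synthesis, glycolysis, mitochondrial and homeostatic microglia genes did not pass camera. All 23 rod phototransduction genes were lower in these cells too (median -1.65), as were 8 of 12 cone phototransduction genes. The lists with a direction above passed camera, with adjusted p from 0.233 to 0.384 with an estimated correlation. The share of rods among all cells was lower in the same mice. Bleaching raised 2551 and lowered 2252 of 14571 genes, and leaving out 1 mouse gave totals from 3432 to 4162. Cluster 4 held 66.86% of Müller glia in unbleached and none in bleached PVR mice, and cluster 8 held 65.15% after bleaching.

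PVR cones lost RNA of their own phototransduction genes. The opsins Opn1sw and Opn1mw fell by -1.94 ± 0.37 and -2.1 ± 0.42, cone arrestin Arr3 by -1.5 ± 0.33 and the channel subunit Cngb3 from 4050 ± 391 to 1520 ± 434 CPM, while the phosphodiesterase subunit Pde6c rose (0.49 ± 0.14). Of 12 cone phototransduction genes, 7 fell and 1 rose (median -1.01; camera adjusted p = 0.000779; adjusted p = 0.225 with an estimated correlation). Eif2ak3, the stress kinase PERK, rose from 43.7 ± 1.76 to 313 ± 108 CPM, with 8 of 22 unfolded protein response genes higher (median 0.52; adjusted p = 0.0979 with an estimated correlation). Mitochondrially encoded genes fell in 5 of 7 cases, with mt-Nd5 at -0.96 ± 0.21 (adjusted p = 0.214 with an estimated correlation). Gliosis genes rose in 11 of 13 cases in cones and 11 of 18 in bipolar cells (adjusted p = 0.0936 and adjusted p = 0.0591 with an estimated correlation), and interferon genes in 3 of 5 and 6 of 13 (adjusted p = 0.0979 and adjusted p = 0.0594 with an estimated correlation). RNA of rods fell in the same cells, with 20 of 23 rod phototransduction genes lower in cones and 22 of 23 in bipolar cells (adjusted p = 0.0251 and adjusted p = 0.0591 with an estimated correlation). Müller glia went from 4.74% to 19.12% of the cells in these mice, and glial RNA in cones and bipolar cells was not tested. In cones 1093 genes rose and 1001 fell (1261 in total without S27). In bipolar cells 690 rose and 647 fell (1337 in total, 763 without S16 and 743 without S27). Cluster 3 held 99.47% of PVR cones before and 13.32% after bleaching, and cluster 11 held 0.53% and 86.68%.

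Ceramides are named in the study's purpose, and 2 of the fixed lists hold the genes of their metabolism. Single genes changed in both directions on bleaching in PVR mice. In Müller glia the phosphate-forming ceramide kinase Cerk rose by 1.16 ± 0.23 (55.9 ± 5.07 to 124 ± 12.7 CPM), Sgpl1, which degrades sphingosine phosphate, by 1.33 ± 0.26, and the acid ceramidase Asah1 by 0.4 ± 0.15. The ceramide synthases Cers2 (0.85 ± 0.22) and Cers5 (0.7 ± 0.19) rose and Cers4 (-0.84 ± 0.15) and Cers6 (-0.56 ± 0.2) fell, and Sptssb, a small subunit of serine palmitoyltransferase, went from 15.5 ± 2.76 to 2.07 ± 0.519 CPM. In rods Cerkl, a relative of ceramide kinase, rose from 334 ± 13.5 to 997 ± 50.2 CPM (1.58 ± 0.27), and the ceramide carrier Cert1 (-0.77 ± 0.15) and Kdsr, of ceramide synthesis (-0.68 ± 0.13), fell. By list, 2 of 18 synthesis genes rose and 4 fell in PVR Müller glia, and 10 of 25 breakdown genes rose and 2 fell (median 0.15; camera adjusted p = 0.0924; fry adjusted p = 0.00111). In PVR rods 2 of 19 synthesis genes rose and 3 fell, and 2 of 23 breakdown genes rose and 4 fell. For synthesis the median and mean differ in sign, at 0.12 and -0.14 in Müller glia and 0.09 and -0.01 in rods, with camera in the direction of the mean (adjusted p = 0.648 and adjusted p = 0.731). For breakdown in rods the median was 0.02 and the mean 0.1, with camera in the lower direction (adjusted p = 0.731). Neither list passed camera in any of the 36 contrasts of each over rods, Müller glia, cones and bipolar cells (lowest adjusted p 0.149 and 0.0924). Adipor1, a receptor with ceramidase activity, did not pass the test on bleaching in PVR rods (0.15 ± 0.12, adjusted p = 0.388) or Müller glia (-0.19 ± 0.16, adjusted p = 0.356).

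Chemokine genes were read in microglia and Müller glia. In microglia Ccl3 was at 213 CPM, Ccl4 at 276 and Ccl5 at 8.27. The groups had 10 to 32 microglia each, too few for a test of genes. In PVR Müller glia 4 of 8 measured chemokine genes rose on bleaching (median 1.64; camera adjusted p = 0.0119; adjusted p = 0.233 with an estimated correlation). Cxcl12 rose from 2.47 ± 1.59 to 20.9 ± 0.918 CPM, and Ccl2, which attracts monocytes, was at 0.103 ± 0.178 and 5.93 ± 3.34 CPM.

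Over rods, Müller glia, cones and bipolar cells, 177 of 774 list tests passed camera. Of these 177, 64 also passed fry and 6 also passed camera with an estimated correlation. The 6 are immediate early genes in DKO and PVR cones and glycolysis in PVR cones, each against WT, rod phototransduction genes in PVR cones on bleaching (adjusted p = 0.0251), sterol synthesis genes in DKO cones with maraviroc (median -0.19, adjusted p = 0.043) and reactive microglia genes in DKO bipolar cells on bleaching (median 0.83, adjusted p = 0.0117). Those against WT share the same unbleached WT mice and are not independent results.

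**Figure D3:**
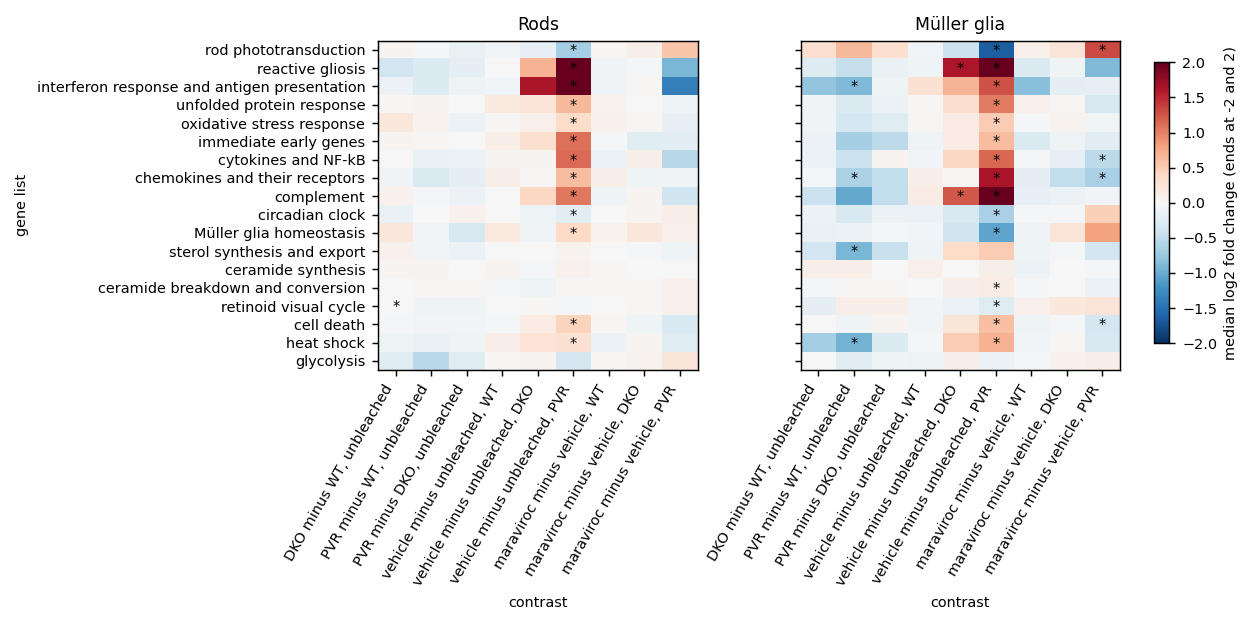
Median log2 fold change of 18 of the fixed gene lists in rods and Müller glia for 9 contrasts (colour, ends at -2 and 2), with a star where the fry adjusted p is under 0.05. The strongest colours are in PVR mice on bleaching, where interferon genes in rods have a median of 4.2 and gliosis genes in Müller glia a median of 3, and the ceramide lists stay near 0.

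The response to bleaching was then compared between genotypes as a difference of differences. In rods, 620 genes had a more positive and 518 a more negative response in PVR than in WT mice, and in Müller glia 1039 and 928. In cones the counts were 210 and 251. Between PVR and DKO, 51 and 8 genes differed in rods and 49 and 121 in cones. In Müller glia edgeR called 0 for PVR and DKO, with 2364 unadjusted p values under 0.05, 167 calls by DESeq2 and 301 by limma. For DKO and WT it called 0 in rods, Müller glia and cones, with 1051, 939 and 535 unadjusted p values under 0.05, 18, 1 and 0 calls by DESeq2 and 0 by limma in each (77 in rods without S22). Without the filter these 4 counts of 0 were 964 for PVR and DKO and 332, 285 and 62 for DKO and WT. Of the 181 genes that rose in DKO rods, 158 also rose in PVR rods (23.2 for independent draws), and of the 61 in Müller glia, 57 did (10.7). Many of these totals change when 1 mouse is left out. The 1138 genes in rods for PVR and WT became 592 without S10, 692 without S11, 624 without S17, 738 without S21 and 691 without S27. The 1967 in Müller glia became 873, 1148, 1000, 1298, 1241, 1294 and 1095 without S10, S11, S16, S20, S21, S25 and S27. The 461 in cones became 198, 294, 306, 206, 280, 290, 282 and 204 without S10, S11, S12, S16, S20, S21, S25 and S27. For PVR and DKO, the 59 in rods became 7, 12, 95, 5, 8, 12, 29, 21, 33 and 12 without S13, S15, S16, S17, S18, S23, S24, S25, S26 and S27, and the 170 in cones became 53, 71, 29, 103, 74, 76 and 42 without S13, S15, S16, S18, S23, S25 and S27. As the mean of the 3 genotypes, bleaching raised 1401 and lowered 1317 genes in rods, and raised 1639 and lowered 1353 in Müller glia.

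**Figure D4:**
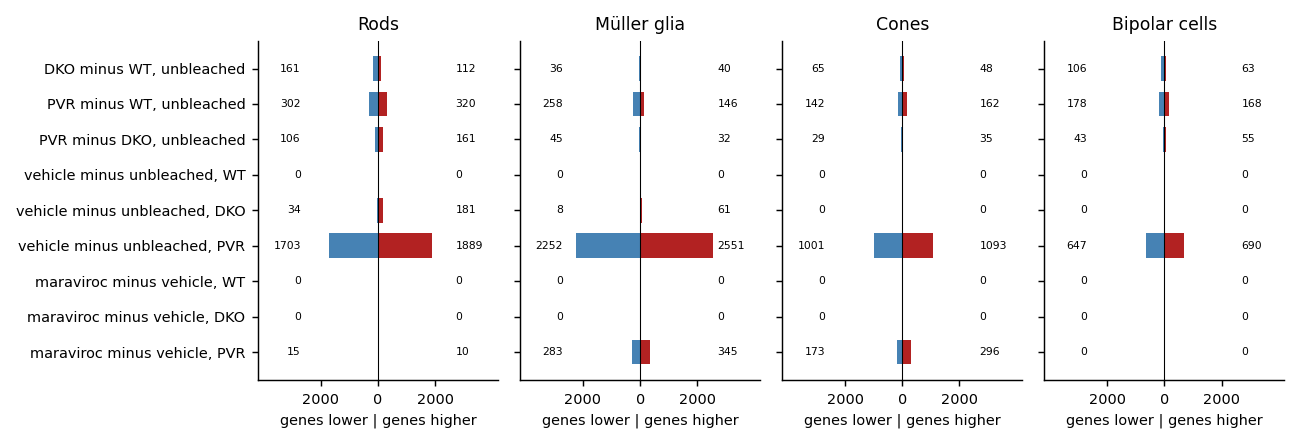
Genes higher (red, right) and lower (blue, left) at an adjusted p under 0.05 in rods, Müller glia, cones and bipolar cells, by contrast, with the counts beside the bars. Bleaching in WT mice has 0 in each class, and bleaching in PVR mice has 1889 higher and 1703 lower genes in rods.

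Maraviroc was compared with vehicle in bleached mice, which asks whether the drug alters the response. In PVR Müller glia, several genes that changed on bleaching were at levels between those of vehicle and unbleached mice. The same vehicle mice stand in both contrasts, which alone makes genes extreme in them seem to move back. A planned test instead took genes called by bleaching in the mean of WT and DKO mice. Since 0 genes were called there, it could not be run, and a reversal by the drug is not shown. Spc25 went from 135 ± 26.8 CPM with vehicle to 560 ± 413 with maraviroc (2.05 ± 0.43, adjusted p = 0.0195), Hes5 from 1.69 ± 0.98 to 12.9 ± 12.7, and Syt10 from 10 ± 2.28 to 54.0 ± 41.0. Lower with maraviroc were the growth factors Hbegf (98.7 ± 19.4 to 21.2 ± 26.1 CPM) and Clcf1 (-1.83 ± 0.41), Casp8, an initiator of cell death (-1.45 ± 0.31), and Bcl2l1, which inhibits it (-0.97 ± 0.19). Gfap was at 201 ± 115 CPM against 476 ± 34.2, which did not pass the test (-1.23 ± 0.59, adjusted p = 0.212). Of 17 homeostasis genes 4 rose, and 10 adjusted over the list alone (median 0.8; camera adjusted p = 0.000655; adjusted p = 0.415 with an estimated correlation). Of 24 gliosis genes none passed the test (median -0.88; camera adjusted p = 0.000535; adjusted p = 0.423 with an estimated correlation). Cers4 (0.7 ± 0.15) and, with overlap between the mice, Sptssb (2.15 ± 0.59) rose among 18 ceramide synthesis genes (median -0.03 and mean 0.1, with camera in the higher direction, adjusted p = 0.856), and of 25 breakdown genes Sgms2 fell (-1.55 ± 0.41). Among 8 chemokine genes 1 fell, Ccl2, at 0.625 ± 1.08 CPM. RNA of rods was higher in the same cells, with 19 of 23 rod phototransduction genes higher (median 1.32; adjusted p = 0.256 with an estimated correlation; fry adjusted p = 0.0122).

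In PVR cones with maraviroc, 6 of 12 cone phototransduction genes (median 0.93; adjusted p = 0.182 with an estimated correlation) and 6 of 7 mitochondrial genes (median 0.93; adjusted p = 0.0998 with an estimated correlation) were higher than with vehicle, among them mt-Nd4 (1.11 ± 0.22) and, with overlap between the mice, Opn1sw (1.65 ± 0.37) and Cngb3 (1.19 ± 0.26). At the same time 16 of 23 rod phototransduction genes were higher (median 0.88; adjusted p = 0.0802 with an estimated correlation). In PVR rods, the receptor Drd4 rose from 53.9 ± 2.79 to 147 ± 62.5 CPM, and Adar, an RNA-editing enzyme that interferon induces, fell from 122 ± 9.23 to 63.6 ± 23.7. Interferon and gliosis genes in rods had medians of -1.37 and -0.91, and rod phototransduction genes 0.55, with none called over all genes tested. These 3 lists passed camera (adjusted p = 0.293 with an estimated correlation for each). The cells of the 2 groups were spread differently over the clusters, with the cells of the mice of a group pooled. Mice weigh unequally there: S34, S35 and S36 gave 2421, 1109 and 1267 rods and 202, 301 and 165 cones. Cluster 11 held 86.68% of PVR cones with vehicle and 25.15% with maraviroc, and cluster 3 held 13.32% and 74.85%. Cluster 8 held 65.15% and 31.36% of Müller glia, and cluster 2 held 61.98% and 24.85% of rods.

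In PVR mice maraviroc raised 10 and lowered 15 genes in rods, 345 and 283 in Müller glia and 296 and 173 in cones. The calls in Müller glia include genes over 5 times higher in rods, and fewer genes were called without those. Bipolar cells had 0 by edgeR, with 1461 unadjusted p values under 0.05, 54 calls by DESeq2 and 82 by limma, and 418 without S36 and 527 without the filter. In WT and DKO mice edgeR called 0 in rods, Müller glia, cones and bipolar cells, with 215 to 442 unadjusted p values under 0.05 and 0 calls by DESeq2 and limma. Without the filter the counts were 6, 41, 2 and 18 in WT and 22, 92, 11 and 33 in DKO mice. The difference in the response to maraviroc between PVR and WT was not called for any gene in rods or Müller glia, with 1094 and 1386 unadjusted p values under 0.05, 0 calls by DESeq2 in each and 105 and 59 by limma. Without S36 this difference was called for 355 genes in rods and 689 in Müller glia, and without the filter for 329 and 465. With all mice a response specific to PVR mice was thus not shown, and the count depends on S36 and on the filter. In cones the difference was called for 0 genes with all mice (1115 unadjusted p values under 0.05, 12 calls by DESeq2 and 23 by limma) and for 642 without S36 and 289 without the filter. The 3 PVR maraviroc mice were unlike. Over the 61 genes that rose in DKO Müller glia, the PVR vehicle mice were on average 2.37, 2.38 and 2.34 above the unbleached PVR mean on the log2 scale, and maraviroc mice S34, S35 and S36 were 1.65, 0.72 and 2.11 above it. Without S36 the counts were 1476 in rods, 3038 in Müller glia and 1816 in cones. The 25 genes in rods became 2, 5, 13, 0 and 0 without S25, S26, S27, S34 and S35. The 628 in Müller glia became 2, 104, 15, 3 and 1 without the same mice, and the 469 in cones became 35, 16, 22 and 4 without S25, S27, S34 and S35. A fit of the compared mice alone called 0 in each of the 3 classes, DESeq2 called 344 in rods and 1253 in Müller glia, and limma called 988 and 977.

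Rods were a smaller share of the cells in bleached PVR mice. Their share of all cells was 80.78 ± 6.24% in unbleached, 40.89 ± 3.92% in vehicle and 56.59 ± 12.55% in maraviroc PVR mice. The last had 71.08% (S34), 49.09% (S35) and 49.61% (S36), each above the highest vehicle mouse (45.39%). S34 lay farthest from vehicle and carries a large part of the difference. In WT mice it was 72.08 ± 8.66%, 71.62 ± 3.86% and 71.23 ± 3.38%, and in DKO mice 68.96 ± 4.79%, 70.44 ± 5.16% and 71.54 ± 7.37%. Müller glia were 4.74 ± 2.42%, 19.12 ± 1.87% and 9.57 ± 3.82% of the cells of PVR mice, bipolar cells 6.97 ± 2.07%, 24.36 ± 4.77% and 18.33 ± 6.35%, and microglia 0.14 ± 0.11%, 0.45 ± 0.07% and 0.18 ± 0.08%. A fall in 1 share raises the others, so these are not numbers of cells per retina. In PVR mice the exact permutation test gave p = 0.1 on bleaching for rods, Müller glia, bipolar, amacrine and horizontal cells, microglia, astrocytes and pericytes, the smallest p that 3 mice against 3 allow, and p = 0.2 for cones. Between maraviroc and vehicle the exact permutation p was 0.1 for rods, Müller glia, microglia and astrocytes, 0.3 for bipolar cells and 1 for cones. It was also 0.1 for cones on bleaching in DKO (-1.69 points) and with maraviroc in WT mice (-0.52). Without bleaching the exact permutation p was 0.1 for horizontal and ganglion cells in both mutants against WT, for astrocytes in DKO and endothelial cells in PVR against WT, and for amacrine cells and astrocytes between PVR and DKO. Over the 3 genotypes, the rod share was lower on bleaching by -12.96 percentage points (permutation p = 0.0579, adjusted p = 0.116) and that of Müller glia higher by 4.64 (permutation p = 0.0566, adjusted p = 0.116). With maraviroc the rod share was higher by 5.47 points (permutation p = 0.148) and that of Müller glia lower by -3.16 (permutation p = 0.0993), both with adjusted p = 0.544. None of the 11 classes passed after adjustment.

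**Figure D5:**
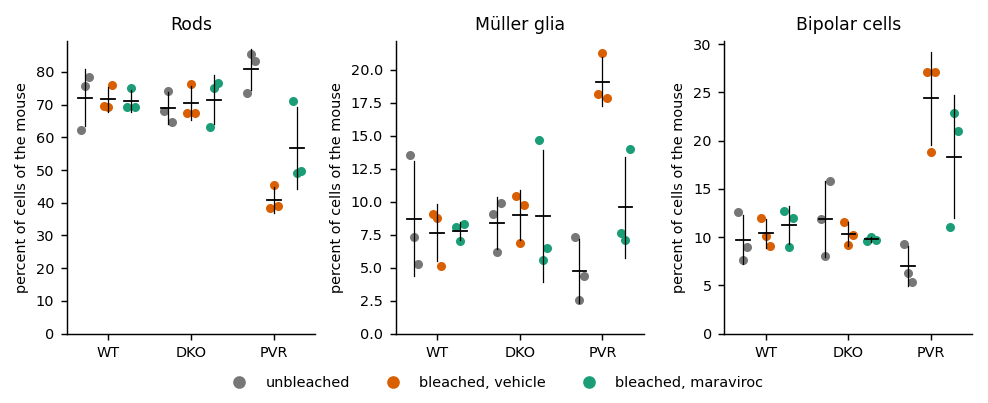
Share of rods, Müller glia and bipolar cells among all cells of each mouse in percent (points), with the mean and SD of 3 mice (lines), by genotype and treatment. In PVR mice rods go from 80.78% unbleached to 40.89% with vehicle and 56.59% with maraviroc.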

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

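The tests of label swaps, of sex, of free rod RNA and of other splits of the mice in rods were chosen after the results were seen, and those of flanking DNA and of other splits in the other classes before. For 5 differences in the response to bleaching between genotypes, 25 splits of the same mice were drawn. In Müller glia 1967 genes differed in response between PVR and WT, and the real split was the 1 highest of 25 drawn (highest other 1277). That rank is the best that 25 splits allow and is not adjusted over the contrasts so tested. In rods 1138 genes differed between PVR and WT, but 3 of 25 splits gave as many (highest other 1408), and 59 differed between PVR and DKO, but 3 of 25 gave as many (105). In cones 461 genes differed between PVR and WT with 3 of 25 splits as high (876), and 170 between PVR and DKO with 3 of 25 as high (294). Chance is neither excluded nor shown by these splits for the 5 counts. The splits exchange genotype labels within each treatment, so they keep part of the effect of bleaching in PVR mice and are not a baseline without change. A split that exchanges more labels in 1 treatment than in the other also turns part of the difference between genotypes into a difference of responses.

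Mice of 1 bleached mutant group differed in response. Over the genes that bleaching raised in Müller glia of the other mutant, the maraviroc mice ranged from 0.72 (S35) to 2.11 (S36) in PVR and from 0.06 (S33) to 0.79 (S31) in DKO, on the log2 scale. A swap of a vehicle and a maraviroc label stays open in both mutants. In PVR the highest maraviroc mouse, S36, differed from the lowest vehicle mouse, S27 (2.34), by -0.23, and in DKO maraviroc mouse S31 lay 0.51 above vehicle mouse S22 (0.28). Both gaps are smaller than the range of the maraviroc mice. Sex stays open too, with male minus female differences of -0.36 and 0.6 in DKO and -0.04 and 0.92 in PVR, from 1 male per group, and a difference in uptake of the drug or in damage by the light was not tested.

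Many genes differed between genotypes without bleaching. DNA flanking the 2 edited genes as the whole cause is argued against, since 220 of the genes called between DKO and WT rods lie more than 50 gene places from both. As a part it stays open: 3.5% of 200 genes near them were called, against 1.67% elsewhere (Fisher's exact p = 0.0864). Which of the genes named above, Col5a3 among them, lie near the edited genes is not given here. Between PVR and WT the percentages were 2.5 and 4.14 (Fisher's exact p = 0.366) and between PVR and DKO 1 and 1.73 (Fisher's exact p = 0.589). Sex as the whole cause is argued against, since 238 genes were called with sex as a covariate. Breeding of the lines apart from each other, which the design does not separate from the edited genes, was not tested, nor was the loading of the unbleached WT mice in 2 wells.

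Rod transcripts fell in the Müller glia of bleached PVR mice. Free RNA of broken rods is a candidate explanation: 104 genes over 5 times higher in rods that were not called in rods themselves had a median of -1.28 in Müller glia (quartiles -1.56 and -0.98) and of -0.17 in rods. The share of rods in the same mice was lower, so less rod RNA per Müller cell would follow without a change in Müller glia. As the whole cause of the changes in Müller glia it is argued against, since 4394 genes were called without the genes over 5 times higher in rods. Rod RNA taken up by living Müller glia was not separated from free RNA. Glial RNA in rods, cones and bipolar cells was not tested.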

How the results depend on the processing

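The fits with sex as a covariate, limma on the deposited log values, without the highest Scrublet scores and without cluster 9 were chosen after the data were seen, the other alternatives before. No paired analysis was possible because the loading IDs match no title, so mice carry no replicate numbers. A minimum of 50 cells per mouse left the mice of rods, Müller glia, cones and bipolar cells as they were, and could not be fitted for endothelial cells. In amacrine cells it gave 8 genes for maraviroc in PVR mice, where 0 were called. Of 864 counts of genes under alternatives other than leaving out a mouse, 682 stayed within 1.5 times, and of 809 that left out a mouse, 640 did. Of 2256 values of named genes without 1 mouse, 544 no longer passed and 5 newly did, and of 3716 under other alternatives 262 and 17. Of 294 gene list results under fry or an estimated correlation, 236 no longer passed. Of 36 levels of Abca4 and Rdh8 in rods or all cells, scaling by TMM moved 2 by over 1 SD, Abca4 in rods of unbleached WT (2850) and of vehicle PVR mice (1620). Depth and the number of mice limit small changes: in simulated data 26.9% of genes in rods and 9.0% in Müller glia were recovered at 1.5 times.

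Without the filter on low counts, which tests more genes, the counts in rods were 446 for DKO and WT, 442 for PVR and DKO, 19, 912 for bleaching in WT and DKO, and 6, 22 and 964 for maraviroc in WT, DKO and PVR. In Müller glia they were 31 and 828 for bleaching in WT and DKO and 41, 92 and 1746 for maraviroc in WT, DKO and PVR. In fits of the compared mice alone, which estimate the spread from those mice only, rods gave 1029 for PVR and WT, and 0 for maraviroc in PVR, as did Müller glia (0). With sex as a covariate rods gave 326 for bleaching in DKO and 60 for maraviroc in PVR, and Müller glia 125 for bleaching in DKO. DESeq2 gave 405 and 344 for the same contrasts in rods and 233 and 1253 in Müller glia, and limma gave 0 and 988 in rods and 35 and 977 in Müller glia. Müller glia gave 33 for bleaching in DKO without the highest Scrublet scores and 121 without cluster 9. For maraviroc in PVR they gave 343 without genes 5 times higher in rods, against 628 with them. That setting keeps the p values and adjusts them over fewer genes, so called genes were among those left out. For the fits of the compared mice alone, sex, DESeq2, limma, Scrublet scores and cluster 9 the cause was not tested.

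Leaving out 1 mouse gave counts in rods of 0 to 843 for bleaching in DKO and 0 to 1476 for maraviroc in PVR, and in Müller glia of 0 to 300 and 1 to 3038. The rod share on bleaching moved between -14.61 and -11.92 and the Müller share between 4.06 and 5.45 points. With maraviroc they moved between 3.06 and 6.88 and between -4.13 and -2.6. By the edgeR test on numbers of cells in place of the permutation test, the log2 change on bleaching was -0.32 in rods (p = 0.00514) and 0.64 in Müller glia (p = 0.0136). As a share of cells other than rods, cones changed sign on bleaching (-5.92) and bipolar cells with maraviroc (1.13). The cone share with maraviroc, 0.16, changed sign without S27 (-0.06) and without S35 (-0.63), with values up to 0.6 without other mice. In each case the cause was not tested.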

Other observations

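The splits of the mice in rods and limma on the deposited log values were chosen after the data were seen, the other tests before. Bipolar cells of unbleached mutants differed from WT in 63 higher and 106 lower genes in DKO and 168 and 178 in PVR mice, of 14031 tested. The total of 169 for DKO was 96 without S10, 107 without S11 and 86 without S14, and the total of 346 for PVR was 186 without S10 and 197 without S11. Bleaching of PVR mice raised 24 and lowered 74 of 7108 genes in endothelial cells, a total of 98 that was 9, 3 and 156 without S17, S25 and S26 and 0 in a fit of the compared mice alone. In amacrine cells 3 rose and 5 fell with 2 unbleached mice, S16 and S17, against 3, since S18 had 3 cells. This total of 8 was 0 without S25, S26 or S27. Without S16 it was 16 and without S17 0, each with 1 unbleached mouse left. With all cells summed, 4348 genes rose and 4095 fell, which includes the change in the shares of the classes.

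Averaged over the 3 treatments, 643 genes were higher and 767 lower in DKO than in WT rods, and 1656 and 1641 in PVR than in WT rods. In Müller glia the counts were 248 and 291 for DKO (539 in total, 887 without S33) and 1999 and 2166 for PVR. These include the response to bleaching. Averaged over genotypes, maraviroc changed 0 genes in rods and Müller glia by edgeR, with 1418 and 1795 unadjusted p values under 0.05, 0 and 39 calls by DESeq2 and 24 and 35 by limma, and edgeR called 266 and 656 without S36 and 431 and 670 without the filter on low counts. The genes that bleaching raised on average in WT and PVR Müller glia had a median of -0.07 with maraviroc in DKO mice (camera adjusted p = 0.000612) and those lowered 0.12 (camera adjusted p = 5.44e-08), but with an estimated correlation each adjusted p was at least 0.852.

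The splits of 3 mice against 3 make 10, too few for a share under 0.05. The real counts and the highest of the other splits in rods were 273 and 0 for DKO and WT, 622 and 0 for PVR and WT, 267 and 1 for PVR and DKO, 215 and 0 for bleaching in DKO, 3592 and 2 for bleaching in PVR, and 25 and 269 for maraviroc in PVR, where 3 of 10 splits gave as many. In Müller glia they were 76 and 55, 404 and 7, 77 and 0, 69 and 1, 4803 and 0, and 628 and 26 for the same contrasts. In cones they were 113 and 0, 304 and 0, 64 and 3, 2094 and 2 for bleaching in PVR, and 469 and 1133 for maraviroc in PVR (2 of 10). In bipolar cells they were 169 and 0, 346 and 0, 98 and 0, and 1337 and 1 for bleaching in PVR. For bleaching in PVR they were 8 and 1 in amacrine cells (2 mice against 3, also 10 splits), 98 and 14 in endothelial cells and 8443 and 1 in all cells, and for maraviroc in PVR 5 and 11 in endothelial cells (2 of 10) and 606 and 100 in all cells. The 5 in endothelial cells became 3, 159, 1 and 0 without S25, S27, S34 and S35. The 606 in all cells became 0, 7, 2, 0, 0 and 3201 without S25, S26, S27, S34, S35 and S36. The 64 in cones for PVR and DKO became 42 without S13 and 37 without S14. In the 28 of 54 contrasts with 0 calls the highest other was 65.

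For means and differences of responses 25 splits were drawn. They keep part of the effects of genotype and bleaching, so they are not a baseline without change, and their shares are not adjusted over the 25 contrasts. They therefore cannot exclude chance. In rods the real split had the most calls for the mean of bleaching (2718, highest other 2224). It also did for genotypes averaged over treatments, with 1410 (133) for DKO and WT, 3297 (1521) for PVR and WT and 1123 (177) for PVR and DKO. In Müller glia the real split had the most calls for genotypes, with 539 (441), 4165 (2180) and 994 (416). It did not for the mean of bleaching, where 2 of 25 splits gave at least 2992 (3100). Where the real count was 0, 25 of 25 splits gave as many. The highest others there were 1275 in rods and 2357 in Müller glia, both for the response to maraviroc between PVR and WT. Splits with so many calls point to a structure of the samples. Such high counts can thus arise from the way the splits are made. Which mice the high splits group together was not tested.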
